A study of Homo sapiens with 4 samples.

How the data were processed

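RNA of 4 samples of the KLM1 cell line was labelled with Cy3 and hybridized to 1 single-colour Agilent array each, per the labels' protocols. The groups, control vector and hairpin against SNAI2, and the replicate numbers 1 and 2 were taken from the sample titles. All 4 arrays lay on 1 slide and carried 1 scan time, per the file headers, so neither could be used as a block. The position on the slide followed the group, so position and group cannot be told apart.

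Spot intensity values were extracted with Agilent Feature Extraction, version 12.1.0.3 per the file headers and version 12.0.3.1 per the submitters' processing notes. The processed signal is a linear intensity after background subtraction and spatial detrending, with a substitute value for dim spots, per the file headers, and was not yet scaled between arrays. Median spot and background intensity and flags of 0 or 1 for signal well above background, saturation and outlier spots were also deposited for each spot. The deposited value table held the same processed intensity times 1 factor per array (5.31, 5.41, 5.32 and 5.29), on a linear scale with genes not centred and with column medians of 62.4, 59.5, 57.3 and 59.7. How the factor was obtained is not given in the sources used here.

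From these files, outlier spots were removed (121, 97, 94 and 106 per array), spots of 1 probe were averaged, and log2 of the processed signal minus the 75th percentile of each array was used. Those percentiles were 202, 207, 202 and 194. Of 58201 probes, 300 were spotted 10 times, and the SD of log2 signal between such repeats, which covers spot noise only, was 0.05 to 0.06. The SD of the difference between replicate arrays was 0.41 for the controls and 0.47 for shSNAI2. The replicates were counted as separate samples because the labels list them so. No spot was saturated. The RefSeq accession of each probe, without its version, was matched to a RefSeq gene table of GRCh38.p14, which named 34975 probes (60.1%), left 23217 under the name given in the files, and was used for names and gene order only, since the array design was annotated on hg19. A further 9 probes had no spot left.

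Probes were kept if well above background on both arrays of at least 1 group (29538 probes), and each gene was tested through its kept probe with the highest mean signal, which gave 23681 genes, 16760 of them with a RefSeq symbol. The test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend on mean signal), with group as the only term, Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Where a probe was not well above background on any array of a group, a bound was computed instead of a fold. For other probes of named genes, disagreements are given beside the gene.

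Before the data were examined, 38 gene lists were fixed from general knowledge, including markers of other cell types and 2 control lists, along with the tests, the alternatives and the rule for named genes. Lists with at least 5 tested genes were tested with limma camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The rule named SNAI2 and IGFBP2. It then took up to 12 genes with the largest positive and 12 with the largest negative log2 difference among those past the threshold. These had to be above background and unsaturated on both arrays of the brighter group, to have separated groups and to carry a gene symbol. From each list it took up to 4 passing members by size, or the 2 with the smallest p where none passed, given as not passing. Some genes that the rule named are not reported here.

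The test was run on simulated data with 50 changed genes per fold among 23681 genes, drawn for shSNAI2 against control. It recovered 1 of 50 genes at 1.5-fold, 3 at 2-fold, 29 at 4-fold and 48 at 16-fold, with 5 false calls. Changes below 4-fold were thus mostly missed in the simulation. In the data 1077 genes passed, which makes the adjustment less strict, so these shares may not apply there. In the simulated list test, 0 of the other lists were called.

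Alternatives covered the normalization, the deposited table, the filter on dim probes, the probe taken for a gene, the spread model, the replicate number as a block, leaving out each array and the gene set test. A planned background correction by normexp (offset 50) on mean spot intensity was not run, since the files hold no such column, and median intensity was used in its place. That setting, scaling by spike-in spots and testing only genes with a symbol were added after seeing the data.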

Results

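Gene expression was measured in KLM1, a cell line from human pancreatic cancer, to ask whether SNAI2 contributes to stem-like properties of these cancer cells. Cells that stably carried a short hairpin RNA against SNAI2 (shSNAI2) were compared with cells that carried the control vector, with 2 samples in each group and 1 single-colour array per sample. Each array held 60901 spots, of which 52.8% and 51.6% were well above background on the control arrays and 52.0% and 53.5% on the shSNAI2 arrays. Values are given as normalized signal, on a scale where the 75th percentile of each array is 100, and as log2 differences of shSNAI2 minus control. The number of arrays limits the precision, and the labels do not state that the replicates came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

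SNAI2, the zinc finger repressor of epithelial genes at which the hairpin was aimed, had normalized signals of 76.5 and 67.6 in control 1 and 2, and of 41.6 and 24.9 in shSNAI2 1 and 2. Both knockdown arrays lay below both control arrays, with a log2 difference of -1.16 (SE 0.30), but the gene did not pass the threshold in limma (adjusted p = 0.0887). IGFBP2, a secreted binding protein of insulin-like growth factors that was picked in advance, had signals of 2943 and 3697 in the controls against 23.1 in shSNAI2 1 and 708 in shSNAI2 2. Its log2 difference was -4.69 (SE 1.49, limma, adjusted p = 0.134). The size of the IGFBP2 difference rested on the choice of knockdown array: it was -2.22 (adjusted p = 0.0441) without shSNAI2 1 and -7.16 (adjusted p = 0.00354) without shSNAI2 2.

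PTN and IGFBP5 were bright in the control cells and not well above background in the knockdown cells, while the cytokine genes IL6 and LTB rose. PTN, the growth factor pleiotrophin, stood at 395 ± 20.4 (SD, n = 2) in the control arrays, was not well above background in either shSNAI2 array, and fell by at least 110.4-fold. IGFBP5, another binding protein of insulin-like growth factors, fell by at least 117-fold from 424 ± 88.8 (SD, n = 2). IL6, an inflammatory cytokine, rose from 18.9 ± 8.85 to 130 ± 66.1 (SD, n = 2 in each group). In all, 413 of 23681 genes rose and 664 fell in limma at an adjusted p under 0.05, together 4.55% of the genes tested, and 371 and 597 of these changed at least 2-fold. The excess of falls depended on genes at background: with probes above background on all 4 arrays, 431 rose and 459 fell. At an unadjusted p under 0.05 in limma, 3140 genes were higher and 2689 lower in the main fit. Of the 1077 genes, each had both knockdown arrays on the same side of both control arrays, an arrangement found for 57.0% of all genes tested, against 33.3% by chance. The counts depended on single arrays: without control 1 or without control 2 none passed (5665 and 3538 genes had an unadjusted p under 0.05 in limma), without shSNAI2 1 there were 11 higher and 146 lower, and without shSNAI2 2 there were 223 and 749. With 2 samples against 2, an exact two-sided test of a single gene could not give a p below 0.333, so each call draws on the spread shared across genes.

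Of the 12 genes named for the size of their fall, 10 had a tested probe that was not well above background on either knockdown array. For these only a bound can be given, set on each knockdown array against the higher of the probe's own signal and the dimmest signal that counted as well above background. Besides PTN and IGFBP5 these were MPPED2, a metallophosphoesterase (at least 95.01-fold lower), DAPL1 (at least 84.2-fold), SLC7A8, a transporter of neutral amino acids (at least 78.3-fold), the secreted olfactomedin-domain genes OLFML3 (at least 69.0-fold) and OLFM1 (at least 32.7-fold), C1orf21 (at least 49.2-fold), AUTS2 (at least 36.6-fold) and SPOCK1, a matrix proteoglycan (at least 33.5-fold). Their adjusted p in limma lay between 0.00115 for PTN and 0.00698 for IGFBP5. Since the knockdown signals were not well above background, the spread within that group may not reflect variation between samples. The same limit holds for the p-value of every gene with a group at background. The bounds also depend on the dimmest signal used, since some brighter probes, such as that of FAP, were not well above background either. The AUTS2 bound applies to its brightest probe, since a second probe was above background on 4 arrays with a log2 difference of -0.74. PAX7, a transcription factor of muscle precursors, fell by 7.44 on the log2 scale, and S100A9, a calcium-binding protein of the calprotectin dimer, fell by 7.43 (limma, adjusted p = 0.0264 and 0.0490), each above background on 1 of the 2 knockdown arrays. The sizes rested on shSNAI2 1, in which both genes were at background: without it the differences were -5.89 and -5.18. A probe for another PAX7 transcript had a log2 difference of -0.63.

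Among the genes named for the size of their rise, UBD, a ubiquitin-like modifier, rose from 51.2 ± 20.96 to 407 ± 73.1 (SD, n = 2 in each group), a log2 difference of 3.04 (SE 0.33, limma, adjusted p = 0.0196). LTB, the cytokine lymphotoxin beta, rose by 3.56 and DOCK10, a guanine nucleotide exchange factor, by 2.77, each with 1 of 2 control arrays above background. The pseudogene TCAM1P rose by 2.94, IL6 by 2.77 and TM4SF18 by 2.74. VIL1, the microvillus protein villin, was at least 3.08-fold higher, with no control array above background, and so were DHRS7C (at least 2.69-fold), C4orf54 (at least 2.68-fold), PTX3, a secreted pattern recognition protein (at least 2.30-fold) and NRROS (at least 3.93-fold). Adjusted p in limma for these genes lay between 0.0127 for TCAM1P and 0.0472 for NRROS. Over the fits without 1 array, the log2 difference of PTX3 ranged from 2.57 to 3.88 and that of NRROS from 2.13 to 3.39. Both ranges rest on control signals that were not well above background, so only the bounds above apply to the size of these rises.

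**Figure D1:**
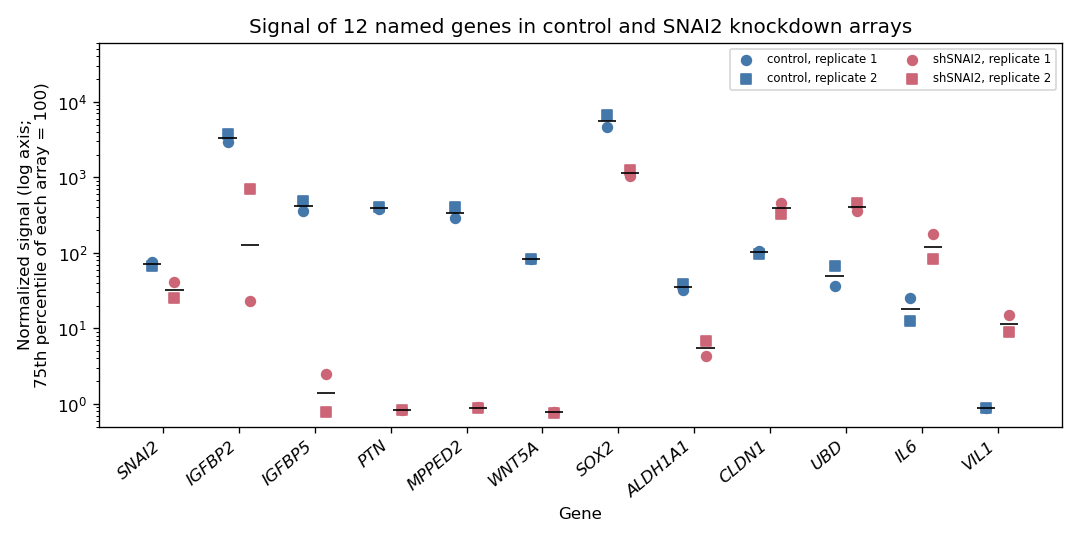
Normalized signal (log axis, 75th percentile of each array at 100) of 12 named genes, with 1 point per array for 2 control and 2 shSNAI2 arrays and a bar at the geometric mean of each group; points include signals not well above background. SNAI2 moves from 76.5 and 67.6 in the controls to 41.6 and 24.9, and the IGFBP2 points of the knockdown arrays lie far apart, at 23.1 and 708.

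Genes of 3 fixed lists, a control list among them, shifted down together and genes of 2 lists shifted up, by camera with a preset correlation between genes. Of 24 measured genes of the NF-kB cytokine and chemokine list, 5 rose and none fell (10 and 0 adjusted over the list alone). Their median log2 difference was 0.68 (limma camera, adjusted p = 0.000852, and 0.989 with an estimated correlation). The list also holds genes that are neither, such as NF-kB subunits, and IL6 and LIF were the only cytokines that passed. IL6 led, followed by LIF, a cytokine of the IL6 family (1.76; a dimmer probe gave 0.62), BIRC3, an inhibitor of apoptosis (1.58), NFKB2, a subunit of noncanonical NF-kB (1.51), and RELB, its partner (1.28, adjusted p = 0.0252), which was chosen after its values were seen. Of 23 YAP and TEAD targets, 2 rose and none fell (4 and 0 adjusted over the list alone), with a median of 0.48 (limma camera, adjusted p = 0.00848; adjusted p = 0.989 with an estimated correlation). These were ANKRD1, a YAP-responsive cofactor (at least 3.98-fold higher), and IGFBP3 (1.08). Of 32 interferon-stimulated genes, 4 fell and none rose (12 and 0 adjusted over the list alone), with a median of -0.47 (limma camera, adjusted p = 0.00157; adjusted p = 0.989 with an estimated correlation): CMPK2 (-3.28), OASL (-2.26), OAS2 (-1.56) and IFIT1 (-1.33).

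Fibroblast and stellate cell markers also fell: 4 of 12 measured genes passed and none rose (6 and 0 adjusted over the list alone), with a median of -0.91 (limma camera, adjusted p = 0.0026; adjusted p = 0.989 with an estimated correlation). COL5A1, a fibrillar collagen chain, fell by 3.47 on the log2 scale, MFAP5, a microfibril protein, by 2.98, and COL6A1 by 2.60. The surface protease FAP, not well above background on either knockdown array, was 3.61-fold lower. Its bound equalled the plain fold of its own signals. Of 5 abundant fibroblast transcripts, COL3A1, DCN and LUM were above background on no control array, and COL1A1 and COL1A2 reached signals of 38.7 and 12.6 there. Without a filter on dim probes the fibroblast list did not pass (limma camera, adjusted p = 0.0595). Of 52 cytosolic ribosomal protein genes, a control list, 2 fell and none rose (4 and 0 adjusted over the list alone): RPS28 (-0.82) and RPS15 (-0.78). The median of this list was -0.17 (limma camera, adjusted p = 1.44e-05, and 0.989 with an estimated correlation). A control list with a small median thus had the lowest p of all lists. A pass at the preset correlation may therefore reflect only a small shared shift, which also limits the other lists that passed.

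The other 33 lists did not pass camera, with adjusted p from 0.207 to 0.97. With an estimated correlation no list had an unadjusted p under 0.05 in limma camera, against 8 with the preset one, and by directional fry 1 list passed, the fibroblast markers (adjusted p = 0.00102), while the mixed form of fry, which counts change in either direction, passed 36 of 38. Median, mean and camera direction did not share a sign in 11 lists: IGF axis, Notch, Hedgehog, MAPK, p53 targets, collagens and laminins, extracellular proteases, stress response, NRF2, classical subtype, and basal-like markers.

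Among the lists closest to SNAI2 function, no factor of epithelial-mesenchymal transition passed over all genes tested, whereas 3 of 13 were higher and 2 lower adjusted over the list alone. SOX9 had a log2 difference of 1.86 (limma, adjusted p = 0.0522) and TCF3 one of -0.82 (adjusted p = 0.0557). ZEB1, ZEB2 and TWIST1 were not well above background in either group. Of 38 epithelial junction genes, 2 rose and none fell (6 and 1 adjusted over the list alone): the tight junction gene CLDN1 (1.94) and the polarity gene LLGL2 (0.97), for which a second probe gave -0.09. Of 24 mesenchymal markers, 2 fell and none rose (3 and 0 adjusted over the list alone), COL5A1 and FAP, although 16 of the 24 had a positive difference and the median was 0.33. Of 19 pancreatic cancer stem cell markers, 1 rose and 2 fell (4 and 3 adjusted over the list alone). The efflux pump gene ABCG2 rose by 1.18, and ALDH1A1, an aldehyde dehydrogenase, fell by 2.70 on its brightest probe, above background on 1 of 2 knockdown arrays (a dimmer probe gave -0.67). MSI2, an RNA-binding protein of stem cells, fell by 1.57. Of 12 pluripotency and self-renewal factors, 2 rose and 1 fell (3 and 2 adjusted over the list alone). SOX2 dropped from 5592 ± 1444 to 1142 ± 141 (SD, n = 2 in each group; log2 difference -2.27, SE 0.22, limma, adjusted p = 0.0160), while the Polycomb gene BMI1 rose by 1.03 and POU5F1 by 0.91.

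Binding proteins of insulin-like growth factors moved in both directions. Of 16 genes of the IGF axis, 2 rose and 3 fell (2 and 3 adjusted over the list alone). IGFBP5 fell as above, the insulin receptor gene INSR was at least 11.9-fold lower and IGFBP6 fell by 1.12, whereas IGFBP3 rose by 1.08 and IGFBP7, chosen after its values were seen, by 1.03 (limma, adjusted p = 0.0242). None of 19 genes of gemcitabine uptake and metabolism passed, over all genes or adjusted over the list alone. The nucleoside transporter gene SLC29A2 had a log2 difference of 0.76 (limma, adjusted p = 0.0746) and RRM1 one of -0.50 (adjusted p = 0.105). Of 10 ABC drug efflux transporters, 3 rose and none fell (3 and 5 adjusted over the list alone): ABCA3 (1.71), ABCC3 (1.39) and ABCG2, while the median of the list was -0.16.

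Of 18 Notch pathway genes, 3 fell and none rose (5 and 1 adjusted over the list alone): the ligand DLL1 (-3.20, 1 of 2 knockdown arrays above background), the glycosyltransferase LFNG (-2.89; another probe gave -0.47) and the target HEY1 (-1.73). Of the 18, 13 had a positive difference, with a median of 0.17, and LFNG stood at -2.22 without shSNAI2 1 and -3.57 without shSNAI2 2. Of 9 Hedgehog pathway genes, GLI3, a transcriptional effector, fell by 2.44, and 2 fell and 1 rose adjusted over the list alone (median of the list 0.03). Of 17 WNT target genes, 2 rose and 2 fell, over all genes and adjusted over the list alone. The ligand WNT5A was at least 23.3-fold lower and the WNT inhibitor APCDD1 at least 12.6-fold lower, while the transcription factors SP5 and TCF7 rose by 1.85 and 1.29. Of 28 TGF-beta and BMP targets, 3 fell and none rose (7 and 3 adjusted over the list alone): the inhibitory SMAD6 (-1.94), BMP4 (-1.29) and ID1 (-1.28). Of 25 MAPK feedback and immediate early genes, the receptor gene EPHA4 fell by 1.83 and none rose (2 lower and 4 higher adjusted over the list alone).

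Of 27 genes of the unfolded protein and integrated stress response, 4 rose and 1 fell (7 and 5 adjusted over the list alone). MANF rose by 1.38, DDIT3, the stress factor CHOP, by 1.36, SDF2L1 by 1.21 and PDIA4, chosen after its values were seen, by 0.97, while the serine synthesis gene PSAT1 fell by 1.36. Of 23 NRF2 targets, 1 rose and 2 fell (1 and 4 adjusted over the list alone). GPX2, a glutathione peroxidase, dropped from 1195 ± 262 to 76.1 ± 27.9 (SD, n = 2 in each group; log2 difference -4.01, SE 0.31, limma, adjusted p = 0.00986), AKR1C1 fell by 1.35 and ABCC3 rose. Of 30 hypoxia and glycolysis genes, the enolase gene ENO2 (2.11) and the phosphofructokinase gene PFKP (1.39) rose and none fell (2 higher and 3 lower adjusted over the list alone). Of 24 cholesterol synthesis genes, EBP fell by 0.70, over all genes and adjusted over the list alone.

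In the growth lists, none of 30 mitosis genes passed, over all genes or adjusted over the list alone, with CCNB2 at -0.62 (limma, adjusted p = 0.0633) and AURKA at -0.81 (adjusted p = 0.0658). Of 32 DNA replication genes, 2 rose and none fell (4 and 2 adjusted over the list alone): the replication factor MCM10 (1.22) and the cyclin gene CCNE2 (1.01). Of 25 p53 targets, 1 rose and 1 fell (2 and 1 adjusted over the list alone), the death receptor gene TNFRSF10B (1.08) and SESN1 (-1.54). Of 28 apoptosis regulators, BIRC3 and TNFRSF10B rose and BCL2L2, a survival gene of the BCL2 family, fell by 1.14 (6 higher and 3 lower adjusted over the list alone). Of 18 genes of MHC class I presentation none passed, over all genes or adjusted over the list alone, with PSME2 at -0.77 (limma, adjusted p = 0.0634) and NLRC5 at 0.65 (adjusted p = 0.121).

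Among matrix genes, 2 of 23 collagens and laminins fell and none rose (3 and 1 adjusted over the list alone), LAMA1 (-3.31) and COL4A5 (-1.50), with 13 of the 23 positive and a median of 0.05. LAMA1 stood at -2.50 without shSNAI2 1 and -4.12 without shSNAI2 2. Of 26 extracellular proteases and inhibitors, the metalloprotease gene MMP7 (1.98) and the inhibitor gene TIMP2 (1.08) rose and none fell (5 higher and 5 lower adjusted over the list alone). Of 16 integrins, ITGB8 fell by 1.31 and none rose (1 lower and 1 higher adjusted over the list alone), although 13 of the 16 had a positive difference and the median was 0.48.

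Of 19 classical subtype markers, MUC1 rose by 1.03 and CEACAM5, a surface glycoprotein, was at least 8.76-fold lower (1 higher and 3 lower adjusted over the list alone). Of 28 basal-like markers, 2 rose and 1 fell (3 and 2 adjusted over the list alone): CST6 (2.47), CALB2 (1.72) and the keratin KRT15 (-1.62). Of 11 simple epithelial and ductal genes, KRT7 rose by 1.45 and SPP1, which encodes osteopontin, dropped from 489 ± 258 to 31.3 ± 8.32 (SD, n = 2 in each group; log2 difference -3.88, SE 0.41, limma, adjusted p = 0.0196), with 2 higher and 2 lower adjusted over the list alone. Of 9 acinar markers, the trypsin inhibitor gene SPINK1 was at least 2.26-fold lower, the only call over all genes or adjusted over the list alone, while 7 of the 9 had a positive difference and the median was 0.14. Of 14 islet and neuroendocrine markers, 1 rose and 2 fell (2 and 4 adjusted over the list alone), among them the prohormone convertase gene PCSK1 (-2.39) and ENO2, which rose. Of 14 leukocyte markers, the receptor gene CSF1R rose by 2.29, the only call over all genes or adjusted over the list alone. None of 6 endothelial markers passed either way, with VWF at -1.81 (limma, adjusted p = 0.1501; another probe gave 0.05) and EGFL7 at -0.61 (adjusted p = 0.185). Of 34 respiratory chain genes, a control list, none passed either way, with NDUFA6 at -0.81 (limma, adjusted p = 0.0525) and ATP5F1C at 0.69 (adjusted p = 0.0625).

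**Figure D2:**
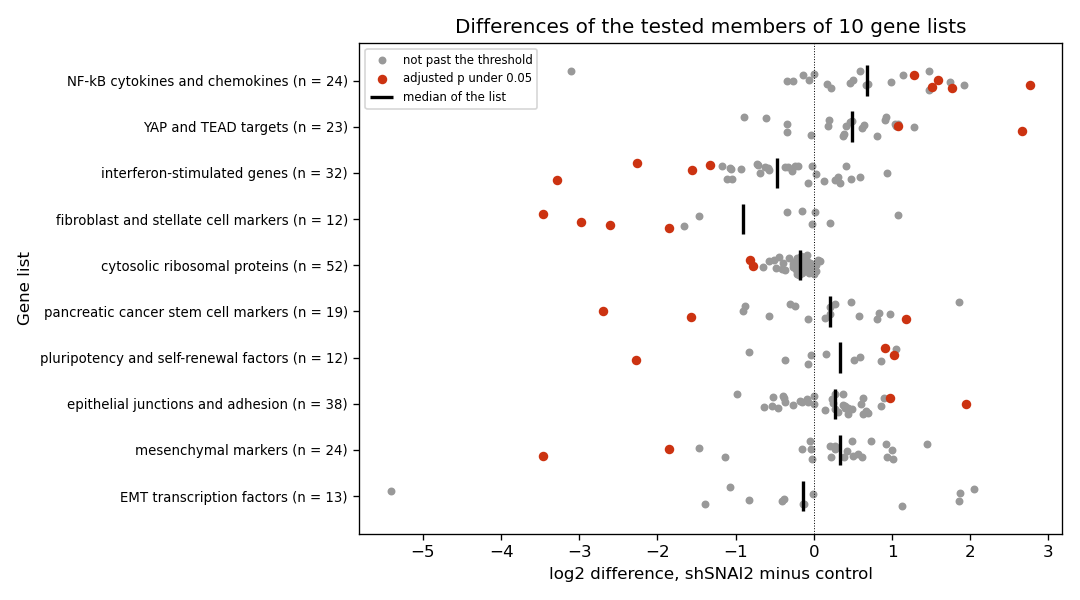
Log2 differences (shSNAI2 minus control) of the measured members of 10 fixed gene lists, with 1 point per gene, red where the adjusted p was under 0.05, and a black line at the list median. The NF-kB list has a median of 0.68 and the fibroblast list one of -0.91.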

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

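Normexp on median intensity, spike-in scaling and testing only genes with a symbol were chosen after seeing the data. Without a filter on dim probes, 0 genes were higher, 0 lower, 0 at least 2-fold higher and 0 at least 2-fold lower in limma (7063 genes had an unadjusted p under 0.05), and 8 lists passed (46778 genes entered that test). Without the trend, 180 genes were higher and 385 lower, and 180 and 385 were so by at least 2-fold. Genes at least 2-fold lower numbered 387 with probes above background on all 4 arrays, a filter that removes genes at background in the knockdown, and 385 with normexp on median intensity. Under normexp the log2 difference of PTN shrank to -3.85 and that of VIL1 to 0.50, so the bounds given above hold for the main processing only. Over the fits without 1 replicate, in which a lone array was assumed to vary like the other group, the range was 0 to 223 genes higher, 0 to 749 lower, 0 to 223 at least 2-fold higher and 0 to 749 at least 2-fold lower. None passed without control 1 (5665 at an unadjusted p under 0.05 in limma) or without control 2 (3538). Camera with an estimated correlation passed 0 lists (0 at an unadjusted p under 0.05) and fry passed 1. Beyond what the construction of a setting explains, the cause was not tested. SNAI2 stayed negative and short of the threshold in all 19 settings, from -0.71 to -1.53, with adjusted p from 0.0684 to 0.298. No named gene or list changed sign past a threshold. Leaving out 1 array moved the difference of 11 called named genes by over 1.5-fold. These were PTX3, NRROS, IGFBP5, DAPL1, PAX7, S100A9, INSR, APCDD1, CEACAM5, LFNG and LAMA1. Of the 107 named genes, 93 had a call, and 93 of 93 lost it without the filter and without either control, 69 without shSNAI2 1, 37 without shSNAI2 2 and 44 without the trend. Scaling ended at most 8 calls per setting, among them POU5F1, TNFRSF10B, TIMP2, IFIT1, OAS2, IGFBP3, NRROS, CALB2 and AKR1C1. Averaging the probes of a gene ended 9 (LLGL2, BMI1, POU5F1, TCF7, LFNG, CCNE2, LIF, LAMA1 and AKR1C1). The NF-kB, YAP, interferon and ribosomal protein lists passed in 19 of 19 settings and the fibroblast list in 18. Replicate numbers did not pair the arrays (r = 0.0453 across genes, which are not independent, between the control and the shSNAI2 differences of 1 minus 2). The replicate block gave 385 genes higher and 689 lower, 374 and 667 by at least 2-fold, and ended 13 named calls. Slide or scan as a block and normexp on mean intensity were not run. Leaving out saturated probes could move nothing, since no spot was saturated. That setting equals the main fit, and both are counted among the 19 settings. Signal over background limits the genes at background to bounds.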

Other observations

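Several tests were chosen only after the result was seen: the gene-order windows, their comparison with the control pair, the comparison of hybridization between groups and the comparison of the directions in which single probes went to background. All genes named in the next paragraph were chosen after their values were seen, unless named in the report.

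More genes were at background in the knockdown cells and bright in the controls than the reverse. Of the genes that fell, 217 were above background on both control arrays and, by any of their probes, on neither knockdown array, 44 of them by at least 10-fold, whereas 38 genes showed the opposite arrangement, 0 of them by at least 10-fold. The set of 44 held both the growth factor PTN and PTPRZ1, a receptor for it (at least 24.5-fold lower, limma, adjusted p = 0.00698). It also held the transcription factor SOX21 (at least 29.0-fold), a relative of SOX2, which fell too. Others were S100A8, the partner of S100A9 (at least 71.2-fold), the heparan sulfatase SULF1 (at least 25.6-fold), the matrix gene FRAS1 (at least 34.5-fold), the chemokine receptor ACKR3 (at least 20.8-fold) and the WNT antagonist SOST (at least 14.99-fold).

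The knockdown replicates differed most in genes of growth factor signalling, also chosen after their values were seen. BAMBI, a decoy receptor of the TGF-beta family, had signals of 10.6 and 783 in shSNAI2 1 and 2, against 909 and 639 in the controls. The imprinted genes H19 (52.9 and 1161, controls 296 and 290) and IGF2 (11.8 and 160, controls 425 and 433) and the ligand BMP7 (5.39 and 103, controls 2428 and 2618) had gaps in the same direction as IGFBP2. SNAI2 itself had a log2 difference of -0.74 between shSNAI2 2 and 1. Of 401 genes that fell and were above background on all 4 arrays, 136 (33.9%) were lower in shSNAI2 2 than in 1, and of 370 that rose, 127 (34.3%) were higher in shSNAI2 2. Within the controls, VIM stood at 680 and 84.3 (1146 and 373 in shSNAI2) and the keratin KRT6A at 5078 and 453.

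For the genes bright in both controls and at background in both knockdown arrays, 3 accounts were tested. The set was taken by the tested probe alone with a bound of at least 10-fold (47 genes, AUTS2 among them). Failure of single probes would leave other probes unchanged, but 9 other probes of 8 genes had a median log2 difference of -4.01 (95% bootstrap interval -5.33 to -1.34), with AUTS2 at -0.74. For the 39 genes without such a probe, random failure would strike control arrays as often, which 0 genes showed at the same bound of at least 10-fold (upper 95% exact binomial limit 9.03%). That comparison restates the imbalance already seen between the groups, so it adds no separate evidence for these 39 genes. Weaker hybridization would lower the share of spots above background, which was higher by 0.536 percentage points in the knockdown arrays (52.8% against 52.2%). Loss of chromosomal segments would pull down genes up to 2 places away in gene order to a median of -1 or less. With genes of the set itself left out, the median of 153 such neighbours was -0.148 (95% bootstrap interval -0.255 to -0.0508, quartiles -0.780 and 0.164). They lay slightly lower than all tested genes with a symbol, whose median was 0.0585. The neighbours' median argues against segment loss as the whole cause. However, the interval reaches slightly past the bound set in advance, and the rule was loosened to the median after it was seen. Still, 4 of the 40 genes with a symbol, WNT5A with CACNA2D3 and MPPED2 with LOC102723403, lay within 2 places of another, against 0.378 on average in 10000 random draws (permutation p = 0.0162), and an effect of the SNAI2 hairpin or of clonal origin may account for the rest, neither of which the design separates.

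Neighbouring genes shifted together in the knockdown arrays. With genes past the threshold left out and complete windows only, the spread of running medians over each gene and the 50 on either side in gene order was 3.19 times that of shuffled orders, above each of 1000 shuffles (permutation p = 0.000999, the smallest they can give), with windows from -0.58 to 0.68, and windows of 25 genes, tried before it over all genes, gave 2.13. The control pair also lay above each of 1000 shuffles, with a ratio of 1.38 (permutation p = 0.000999), so neighbours shifted together there too. The smaller ratio argues against coexpression that is the same in any pair of arrays as the whole account. Between the knockdown replicates the ratio was 3.55. Copy number differences between the cell populations, including between the knockdown samples, are a candidate explanation that these values meet. Signal differences that follow base composition stay open, since no probe sequences were used here, and so does the hairpin itself.

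The fibroblast and stellate cell markers that fell could come from fibroblasts or stellate cells mixed into the control cultures. Those cells bring abundant COL3A1, DCN and LUM, and 3 of the 5 abundant transcripts tested were above background on no control array, which argues against that source. Expression of these genes by the cancer cells themselves, lowered in the knockdown, stays open as a hypothesis.

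Predictions on signal bias of the lists were written before their results and set aside after them, so these are given only as values. Among 10000 random lists matched on mean signal, the ribosomal protein median of -0.17 lay at percentile 0.12 (central 95% from -0.14 to 0.00677), the NF-kB list at 100, the YAP list at 99.98, the fibroblast list at 0.01 and the interferon list at 0. Genes of the random lists were drawn independently of each other, so these percentiles do not allow for correlation between the genes of a list. The arrays can be parted into 2 pairs in 3 ways, too few for a share under 0.05: the real split gave 1077 genes, and the highest of the others 0 in limma (353 at an unadjusted p under 0.05). Each pair of the other splits joined a control with a shSNAI2 array, so the group difference entered the spread within pairs. A count near 0 was thus built into those splits and does not measure false calls.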
